A study of Rattus norvegicus with 22 samples.

How the data were processed

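RNA from germ cells of male rats was measured on 22 Agilent one-colour whole-genome rat arrays. Per the labels, rats received cyclophosphamide, an alkylating anticancer drug, at 6 mg/kg or saline by gavage, 6 days per week for 4 weeks. Pachytene spermatocytes, which are in meiotic prophase, and round spermatids, which are the haploid cells after meiosis, were then separated by sedimentation at unit gravity. Cy3-labelled RNA was hybridised to slides that hold several arrays each.

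The deposited scanner files hold the processed signal of each spot as an intensity, which Feature Extraction had background-subtracted and corrected for trends across the array but had not scaled between arrays. The submitters' notes name Feature Extraction 11.5.1.1, while the file headers name version 10.7.3.1. The authors' value table holds log2 values of 30507 probes. Set against the scanner values, it matched signals quantile normalized within 1 cell type and centred on each probe's median within that cell type. Over probes brighter than the median, its columns correlated with their own array at 0.942 to 1 and with any other array at 0.61 or less. The slopes over these probes were 0.882 to 1.002, and dimmer probes were left out of both measures. The column medians over all probes were -0.0098 to 0.007. The authors' exact steps stay unknown, and the direction and log base follow from that comparison. Because of the centring the value table served as an alternative for the treatment comparisons alone.

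Each array held 62976 spots, of which 58717 were not controls, for 30367 probes. Control spots and spots marked as outliers by Feature Extraction were left out, spots of 1 probe were averaged, and 37 probes had no usable spot on at least 1 array. The analysis used the log2 of the processed signal minus the array's 75th percentile over probes that were not controls. A RefSeq accession named 17998 probes (59.3%) with 15154 symbols through the gene table of assembly GRCr8. The remaining 12369 probes had no symbol in that table and stayed under the file's own name. Where a gene had several probes, the probe with the highest mean over all arrays was used. Among 1873 other probes of genes that passed between the cell types, 1358 passed in the same direction, 230 passed in the opposite direction and 285 did not pass. A probe was tested where it was well above background, which required more than 0.5 of its spots to be, on all but at most 1 array of at least 1 group compared. Where no array of a group had a gene well above background, the fold is printed as at least the ratio of the bright group's mean to the lowest signal well above background. Genes measured above it on some arrays of a group are given with the number of those arrays.

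Differences were tested with limma 3.58.1 (lmFit and eBayes) and statmod 1.5.0 in R 4.3.3, on group means fitted to all 22 arrays, at a Benjamini-Hochberg adjusted p of 0.05. Tables and drawings used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The contrasts were cyclophosphamide minus saline in each cell type, the difference between those effects, and round spermatids minus pachytene spermatocytes of saline rats. The groups held 5 or 6 arrays, each taken as a different rat, and that number limits the precision. The labels do not say whether equal rat numbers within a treatment name the same animal. The cyclophosphamide pachytene arrays numbered 16-2011 and 16-2012 were taken as different rats in the main comparisons. The replicate block for the difference between effects and for cell types joined them as the same rat. The main comparisons treated all arrays as independent. Values with ± are standard errors from limma for fold changes and standard deviations over rats for levels.

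Before the data were examined, 34 gene lists were fixed, 10 of cell type markers and 24 of pathways or complexes. Lists with at least 5 tested members were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01. Camera with a correlation estimated from the arrays and fry were run beside it. The fry p tests whether a list's genes move, on balance, in one direction, its mixed p whether they change in either direction, and neither compares the list with other genes. A shift is the mean log2 change of a list minus that of all tested genes. The red blood cell list had 4 genes on the array and was not tested. The median, the mean and camera differed in sign for 6 lists in pachytene spermatocytes, 4 in round spermatids, 7 for the difference between these effects and 4 between cell types, and none of these lists passed. Counts of members that passed after adjusting p over the list's members only are given as adjusted over the list alone.

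The rule for named genes was also fixed before the data were examined. It took genes with an annotated symbol. In each treatment comparison these were the 10 largest rises and falls that passed and whose groups did not overlap, filled up to 5 per direction by the smallest p where fewer passed. It added the 6 smallest p for the difference between effects, the 8 largest cell type differences per direction, and up to 4 members of each list. Levels per array were compared by exact permutation tests, two-sided, over 36 measures per cell type with Benjamini-Hochberg adjustment.

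The pipeline was tested on simulated data with 200 changed genes per contrast. It recovered 73.1% of genes changed 2-fold and 41.8% of those changed 1.5-fold in pachytene spermatocytes, and 77.6% and 41.8% in round spermatids. The shares were 53.7% and 9% for the difference between effects and 82.1% and 23.9% between cell types. False calls numbered 3, 8, 5 and 6 in that order. A list shifted by 0.3 was recovered each time and no other list was called. This does not carry over to the real arrays, where random relabellings called a median of 5, 6, 5 and 8 lists in the same order.

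The slides and scan days came from the deposited files. Slides 1 and 2, read on scan day 1, each held 1 cyclophosphamide and 1 saline pachytene array and 3 arrays of each round spermatid group. Slides 3 and 4, read on scan day 2, held pachytene arrays alone, 2 cyclophosphamide with 1 saline and 1 with 2. Alternatives were normexp background correction with an offset of 50 on median signals (the files give no mean signal), quantile normalization, median centring, no filter and a stricter filter, every probe, slide as a fixed or random block, each slide alone, the compared groups alone, an intensity trend, array weights, the replicate block, other thresholds, and leaving out each array. No array was left out of the fit.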

Results

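Gene expression was measured in purified male germ cells of rats given chronic cyclophosphamide or saline. The 22 arrays fell into 4 groups: pachytene spermatocytes after cyclophosphamide (n = 5) or saline (n = 5), and round spermatids after cyclophosphamide (n = 6) or saline (n = 6). The 75th percentile of the processed signal lay between 1069.5 and 2423.3 intensity units per array, 65.3% to 76.4% of probes were well above background, and no spot was saturated. Arrays of 1 group correlated at 0.9714 to 0.9914, and the first principal component, which parted the cell types, held 82.8% of the variance. The series title and design ask how chronic cyclophosphamide changes the transcripts of the 2 cell types.

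The first comparison, round spermatids against pachytene spermatocytes of saline rats, gave the background on which treatment acted. The testis-specific linker histone H1f6 was 74.5-fold higher in pachytene spermatocytes (95% interval 55.1 to 101; log2 difference -6.22 ± 0.21; limma adjusted p = 1.26e-15). Gmcl1 was 49.4-fold higher there, Fbxo43, an inhibitor of the anaphase-promoting complex, 40.3-fold, the POU-domain gene Pou5f2 38.0-fold and the kinase Pbk 24.9-fold. Ccp110, which caps centrioles, the fatty acid ligase Acsl3 and the piRNA-binding protein Piwil1 were 24.7-fold, 21.1-fold and 20.3-fold higher in pachytene spermatocytes. Higher in round spermatids were the olfactory receptor Or10al4c by 12.1-fold, Fhdc1 by 12-fold (log2 difference 3.58 ± 0.27), Dnmt3l, a cofactor of DNA methyltransferases, by 11.8-fold (7.81 to 17.8; adjusted p = 1.74e-10), and the olfactory receptor Or10al5b by 11.1-fold. Gfpt2, which feeds hexosamine synthesis, was higher there by 3.42 ± 0.32 on the log2 scale, and Tmem269, Atosb and Hsd17b13 by 10.5-fold, 10.4-fold and 9.59-fold. Or10al4c, Or10al5b and Gfpt2 were well above background on 4 of 5 saline pachytene arrays. The log2 level of Or10al4c was -8.287 on saline pachytene rat 16 and -5.019 to -3.7 on the others of that group. For Gfpt2 it was -7.157 on rat 26 and -5.496 to -5.063 on the others. These single low arrays enlarge the differences of Or10al4c and Gfpt2, and their ranks rest in part on them. For each of these 16 genes no saline array of one cell type overlapped the other. They were picked on the same arrays for their large differences, so this separation adds no independent support, and it was not counted over all genes. H1f6 lies on chromosome 17 from 41855216 to 41855960, Gmcl1 on chromosome 4 from 120697976 to 120737267, and Dnmt3l on chromosome 20 from 10614591 to 10628989 of GRCr8.

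**Figure D1:**
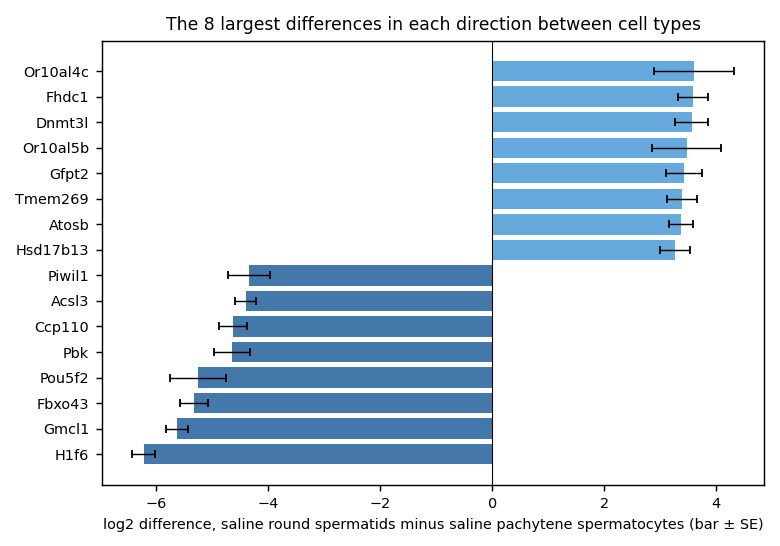
Log2 difference between saline round spermatids (n = 6) and saline pachytene spermatocytes (n = 5) for the 8 genes with the largest difference in each direction, as bars with the standard error. The differences run from -6.22 for H1f6 to 3.6 for Or10al4c, which a single low saline pachytene array enlarges.

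With limma, 14598 of 19401 genes (75.2%) passed between the cell types, 7422 higher in round spermatids and 7176 higher in pachytene spermatocytes. Of these, 4906 and 4017 differed by more than 2-fold. There were 14095 with slide as a block, on slides 1 and 2 together 13257, within slide 1 alone 10433 and within slide 2 alone 11436. Slides 3 and 4 held no round spermatids.

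Genes of spermatid formation were higher in round spermatids as a group. Of the 20 round spermatid markers 19 were higher and 0 lower, led by the kinase Tssk6 (6.66-fold), Spem1 (6.61-fold) and the sperm glycolytic enzyme Gapdhs (6.23-fold). All 10 late spermatid markers were higher, protamine Prm2 by 5.82-fold, and in the list of spermatid differentiation 47 of 57 genes were higher and 1 lower, with Klhl10 5.10-fold and Akap3 4.90-fold higher. The counts adjusted over the list alone were the same. The lists were shifted by 1.99, 1.85 and 1.48 (camera adjusted p = 4.54e-06, 0.00213 and 5.8e-09), and for each the adjusted p = 0.437 with an estimated correlation. Their shifts were 1.79, 1.58 and 1.37 with slide as a block, 1.59, 1.24 and 1.15 within slide 1, and 2.13, 2.02 and 1.65 within slide 2.

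Pachytene markers, piRNA genes and histones were mostly higher in pachytene spermatocytes. Of 18 pachytene markers 12 were higher there and 4 lower, with Piwil1 20.3-fold, the mismatch repair gene Mlh3 12.3-fold and Piwil2 8.81-fold higher. In the piRNA list 12 of 21 genes were higher in pachytene spermatocytes and 4 lower, with Tdrd5 19.7-fold and Fkbp6 4.80-fold higher. In the list of histones and histone chaperones 21 of 33 were higher in pachytene spermatocytes and 11 lower, among them the testis histone H2bc1 (19-fold) and H2ax (5.15-fold). These 3 lists were shifted by -1.09, -1.14 and -1.01 (camera adjusted p = 0.0435, 0.0326 and 0.0335), each with adjusted p = 0.437 with an estimated correlation. The shifts with slide as a block were -1.03 (adjusted p = 0.0716), -1.11 and -1.03, within slide 1 -0.90 (adjusted p = 0.0882), -0.99 and -0.88, and within slide 2 -1.15 (adjusted p = 0.0756), -1.22 and -1.12. The pachytene marker call was also lost without saline pachytene rat 16 or rat 26. The list of synaptonemal complex and cohesin genes went both ways, with 6 of 19 higher in round spermatids and 9 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.566). Sycp2 and Sycp3 were 3.62-fold and 3.53-fold higher in pachytene spermatocytes, and Smc3 and Sun1 3.66-fold and 3.68-fold higher in round spermatids. For cell division in meiosis 18 of 43 genes were higher in round spermatids and 19 lower (camera adjusted p = 0.624), with Cks2 20-fold and Cdk2 13.4-fold higher in pachytene spermatocytes. For DNA and histone modifiers the counts were 17 and 23 of 46 (camera adjusted p = 0.342), with the demethylase Kdm5b 8.34-fold and the methyltransferase Prmt5 8.89-fold higher in pachytene spermatocytes. Except where given, the counts adjusted over the list alone were the same.

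Genes for making and degrading proteins and for respiration were lower in round spermatids. Of 75 cytosolic ribosomal protein genes 49 were lower and 2 higher, with Rpl19 5.42-fold and Rpl10a 2.98-fold lower. In the proteasome 28 of 43 were lower and 5 higher, with the testis subunit Psma8 17.2-fold lower, and in oxidative phosphorylation 49 of 72 were lower and 5 higher, with Atp5mc1 5.40-fold and Uqcrc2 3.03-fold lower. The shifts were -0.64, -0.65 and -0.68 (camera adjusted p = 4.95e-05, 0.00329 and 3.51e-05), with adjusted p = 0.534, 0.437 and 0.437 with an estimated correlation. They were -0.66, -0.62 and -0.71 with slide as a block, -0.74, -0.55 and -0.73 within slide 1 and -0.63, -0.70 and -0.73 within slide 2. Glycolysis genes went both ways, 14 of 30 higher in round spermatids and 10 lower (14 and 11 adjusted over the list alone; camera adjusted p = 0.489), with Eno3 4.86-fold higher in pachytene spermatocytes and Aldoart2 4.35-fold higher in round spermatids. The other counts adjusted over the list alone were the same.

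DNA repair lists, relevant to an alkylating drug, differed in part between the cell types. In nucleotide excision repair 12 of 17 genes were lower in round spermatids and 1 higher, with Ercc8 4.10-fold (well above background on 4 of 6 saline round spermatid arrays) and Xpa 2.03-fold lower. In mismatch repair 11 of 16 were lower and 3 higher, with Pms1 4.60-fold lower. Their shifts were -0.71 and -0.79 (camera adjusted p = 0.0367 and 0.0326), both with adjusted p = 0.437 with an estimated correlation. Blocking on slide gave -0.66 (adjusted p = 0.0714) and -0.74, slide 1 alone -0.62 and -0.66 (adjusted p = 0.0882 and 0.0737) and slide 2 alone -0.76 and -0.76 (adjusted p = 0.0728 and 0.0638). Crosslink repair had 11 of 20 lower and 5 higher, with Ube2t 13.6-fold lower, and homologous recombination 16 of 29 lower and 9 higher (17 and 9 adjusted over the list alone); their camera adjusted p were 0.196 and 0.0894. Base excision repair had 8 of 17 higher and 7 lower, with Parp2 9.48-fold lower (camera adjusted p = 0.836). End joining had 5 of 12 each way, with Dntt 6.32-fold higher (well above background on 2 of 5 saline pachytene arrays) and Nhej1 5.02-fold lower (camera adjusted p = 0.805). Of 26 p53 targets 9 were higher and 11 lower (10 and 11 adjusted over the list alone; camera adjusted p = 0.594), with Mdm2 3.19-fold and Polk 5.01-fold higher and Zmat3 4.65-fold lower. The remaining counts adjusted over the list alone were the same.

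Stress and detoxification lists were mixed. Among glutathione transferases and aldehyde dehydrogenases 22 of 36 were lower in round spermatids and 7 higher (23 and 7 adjusted over the list alone), with Gstm6 6.05-fold and Gsto1 2.98-fold lower. That list was shifted by -0.76 (camera adjusted p = 0.026; adjusted p = 0.437 with an estimated correlation), by -0.81 with slide as a block, -0.76 within slide 1 and -0.86 within slide 2. Antioxidant genes had 15 of 40 higher and 13 lower (camera adjusted p = 0.945), with Txndc2 8.64-fold higher and Sod2 4.28-fold lower. Heat shock genes had 8 of 36 higher and 16 lower (adjusted p = 0.323), with Dnajb9 6.55-fold lower. In the unfolded protein response 7 of 27 were higher and 16 lower (adjusted p = 0.0559), with Syvn1 7.05-fold lower. Apoptosis genes had 12 of 35 higher and 13 lower (adjusted p = 0.805), with Bcl2l14 5.25-fold higher and Htra2 4.70-fold lower. For these 4 lists the counts adjusted over the list alone were the same.

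Markers of somatic testis cells also differed between the purified fractions. Sertoli markers were higher in pachytene spermatocytes for 11 of 17 and lower for 1, with Clu 10.3-fold, Gja1 9.97-fold and the FSH receptor Fshr 8.99-fold higher, Fshr being well above background on 4 of 6 saline round spermatid arrays. All 9 Leydig markers were higher in pachytene spermatocytes, Cyp11a1 by 4.54-fold and Star by 5.26-fold, Star being well above background on 3 of 6 saline round spermatid arrays. In contrast, all 11 macrophage and leukocyte markers were higher in round spermatids, with Lyz2 8.15-fold, Cd74 7.96-fold and C1qa 7.45-fold higher, and so were all 9 peritubular myoid markers, with Acta2 2.99-fold and Myh11 2.71-fold higher. The 4 shifts were -1.63, -1.68, 2.29 and 1.03 (camera adjusted p = 0.00991, 0.026, 0.000952 and 0.0346), with adjusted p = 0.437, 0.437, 0.437 and 0.456 with an estimated correlation. Blocking on slide gave -1.74, -1.73, 2.03 and 0.89, slide 1 alone -1.69, -1.36, 2.28 and 0.96, and slide 2 alone -1.74, -1.92, 2.02 and 1.03. The myoid call was lost with slide as a block (adjusted p = 0.0716), within slides 1 and 2 (0.0843 and 0.105) and without saline pachytene rat 26, and the Leydig call within slide 1 (0.0824). Of 5 endothelial markers 2 were lower in round spermatids (1 adjusted over the list alone; camera adjusted p = 0.805), with Kdr 2.24-fold lower. The counts for the other 4 lists adjusted over the list alone were the same.

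**Figure D2:**
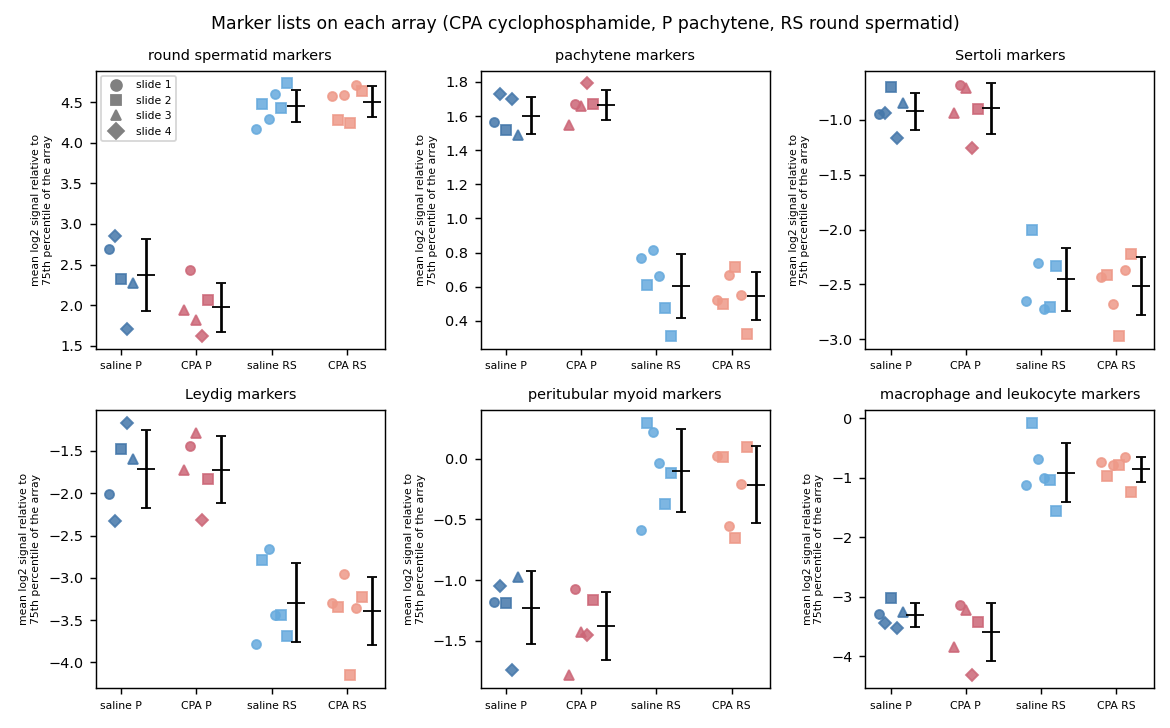
Mean log2 signal of 6 marker lists on each array, relative to the array's 75th percentile, with the group mean and SD beside the points (n = 5 per pachytene and 6 per round spermatid group) and a symbol per slide. Macrophage markers averaged -3.31 in saline pachytene and -0.92 in saline round spermatid fractions.

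The second comparison asked what cyclophosphamide changed in pachytene spermatocytes. No gene passed with limma among 18450 tested (smallest adjusted p = 0.693), so the values that follow describe genes that did not pass. The smallest unadjusted p on the higher side belonged to the class I histocompatibility gene RT1-CE16 (1.24 ± 0.31, a 2.37-fold difference), the zinc transporter Slc39a5 (1.13 ± 0.29), Ly6g6e (1.16 ± 0.34), the tubulin cofactor Tbce (0.45 ± 0.14) and Rpap3 (0.34 ± 0.10), as log2 cyclophosphamide minus saline with n = 5 each. On the lower side they belonged to the receptor phosphatase Ptpro (-0.46 ± 0.11), Pik3ap1 (-0.50 ± 0.12), the olfactory receptors Or52s1b and Or2ag16b (-0.61 ± 0.15), and the VEGF receptor Flt1. Or52s1b and Flt1 were not well above background on any array of the dimmer group, so saline was at least 1.17-fold and at least 1.42-fold higher, and on 4 of 5 saline arrays they were. Ly6g6e was well above background on 4 of 5 saline arrays and Pik3ap1 on 4 of 5 treated arrays. At an unadjusted p under 0.05 there were 1317 genes, 345 higher and 972 lower, and 58 and 151 of them differed by at least 1.5-fold. Independent genes would give 922 by chance. However, of 100 splits of the same arrays into 2 groups 31, the real one included, gave at least 1317 (highest other 5363), so no excess over chance was shown. With slide as a block 0 genes passed (1645 at the unadjusted level), and within slides 1, 2, 3 and 4 there were 5, 1, 1 and 4, with 1 or 2 arrays per group on each slide. For 93.3% of genes the 95% interval lay within 2-fold.

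Transcripts of spermatid formation were lower as lists in the cyclophosphamide pachytene fractions, though 0 of their members passed singly, over all genes or adjusted over the list alone. The 20 round spermatid markers were shifted by -0.40 (camera adjusted p = 1.02e-09), with 19 of 20 below 0 and 10 lower at an unadjusted p under 0.05, including the acrosomal Acrv1 (-0.49 ± 0.18) and Gapdhs (-0.56 ± 0.21). The 10 late spermatid markers were shifted by -0.45 (adjusted p = 4.32e-06), with 10 of 10 below 0, including Akap4 (-0.65 ± 0.25) and Prm2 (-0.65 ± 0.28), and the 57 spermatid differentiation genes by -0.25 (adjusted p = 1.85e-09), with 43 of 57 below 0, including Tssk3 (-0.64 ± 0.23). Each of these lists had adjusted p = 0.545 with an estimated correlation. The mean of the round spermatid markers was 1.97 ± 0.31 after cyclophosphamide and 2.37 ± 0.44 after saline, 4 of 5 treated arrays lay below the saline mean, and the exact permutation p was 0.151 (0.453 adjusted over 36 measures). The shifts were -0.40, -0.46 and -0.24 with slide as a block. Within slides 1 to 4 they were -0.26, -0.25, -0.37 and -0.64 for round spermatid markers, -0.38, -0.36, -0.41 and -0.67 for late spermatid markers, and -0.28, -0.09, -0.16 and -0.39 for spermatid differentiation. Without saline rat 16 the round spermatid shift was -0.26. Genes outside the lists were also compared, among those with a symbol. Those at least 4-fold higher in round spermatids had a median change of -0.40 in the same fractions, relative to genes within 1.4-fold between cell types. Per array the difference was -0.398, or -0.241 without saline rat 16.

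The macrophage list was lower beside them, by -0.29 (camera adjusted p = 0.0197; adjusted p = 0.654 with an estimated correlation), with 10 of 11 markers below 0 and 0 passing singly, over all genes or adjusted over the list alone. Its members included Mrc1 (-0.33 ± 0.12) and Cd74 (-1.06 ± 0.45). Blocking on slide gave a shift of -0.36, and within slides 1 to 4 it was 0.15, -0.40, -0.26 and -0.82. It was below the saline mean on 3 of 5 treated arrays, and the call was lost without cyclophosphamide rat 7 or rat 16-2012, without saline rat 25, where the range over arrays left out was -0.40 to -0.12, and with quantile normalization (adjusted p = 0.0512). Endothelial and peritubular myoid markers were also lower, by -0.21 and -0.15, with 5 of 5 and 8 of 9 below 0, but did not pass (camera adjusted p = 0.0562 and 0.142). Sertoli, Leydig and pachytene markers were shifted by 0.03, -0.004 and 0.07 (camera adjusted p = 0.889, 0.889 and 0.371).

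Genes of respiration, translation, protein degradation and nucleotide excision repair were slightly higher as lists in the same fractions, in which round spermatid markers were lower by the shift of -0.40. All 4 lists were also higher in pachytene spermatocytes than in round spermatids of saline rats. Outside the lists, 925 genes with a symbol at least 4-fold higher in pachytene spermatocytes rose too. Their median change was 0.091 relative to genes within 1.4-fold between cell types, with 23.8% below 0. The rises were therefore not shown to be particular to these pathways. Oxidative phosphorylation was shifted by 0.11 (camera adjusted p = 6.77e-06), with 65 of 72 genes above 0, such as Atp5pf (0.31 ± 0.11) and Atp5f1b (0.27 ± 0.10). Ribosomal proteins were shifted by 0.10 (adjusted p = 9.73e-05), with 69 of 75 above 0, such as Rpl7a (0.31 ± 0.12) and Rpl19 (0.40 ± 0.19), the proteasome by 0.08 (adjusted p = 0.0231), with 35 of 43 above 0, such as Psma4 (0.20 ± 0.10) and Psmb10 (0.21 ± 0.11), and nucleotide excision repair by 0.14 (adjusted p = 0.0376), with 13 of 17 above 0, such as Ercc3 (0.20 ± 0.09) and Gtf2h4 (0.75 ± 0.40). In that order the adjusted p = 0.545, 0.654, 0.654 and 0.545 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. All 5 treated arrays lay above the saline mean for each list. The shifts were 0.13, 0.12, 0.10 and 0.16 with slide as a block, and within slides 1 to 4 they were 0.00, 0.20, 0.16 and 0.13 for oxidative phosphorylation, -0.04, 0.19, 0.17 and 0.15 for ribosomal proteins, 0.07, 0.12, 0.10 and 0.10 for the proteasome and 0.10, 0.12, 0.21 and 0.17 for nucleotide excision repair. Quantile normalization ended the ribosomal and proteasome calls (adjusted p = 0.274 and 0.175). Leaving out an array ended the proteasome call for cyclophosphamide rat 16-2012 and saline rats 25 and 28, and the repair call for cyclophosphamide rats 16-2012 and 29 and saline rats 13, 25 and 28.

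Other DNA damage and stress lists did not pass in pachytene spermatocytes. The p53 targets were shifted by 0.003 (camera adjusted p = 0.964), including Polk at -0.42 ± 0.17, crosslink repair by 0.02 (0.668), homologous recombination by 0.03 (0.466), including Tex15 at -0.40 ± 0.17, mismatch repair by 0.07 (0.165) and base excision repair by -0.09 (0.466). In base excision repair the uracil glycosylase Ung (-1.19 ± 0.34) was the 1 member that passed adjusted over the list alone, and Flt1 was the 1 such endothelial marker, while neither passed over all genes. The other lists had 0 members that passed adjusted over the list alone. Apoptosis genes were shifted by 0.06 (0.355), including Tradd at 0.72 ± 0.22, antioxidant genes by 0.01 (0.826), including Txndc2 at -0.64 ± 0.23, heat shock genes by 0.01 (0.668), including Hspa12a at 0.71 ± 0.23 (well above background on 4 of 5 treated and 2 of 5 saline arrays), and the unfolded protein response by 0.09 (0.056). In all, 8 of 33 lists passed with camera at the preset correlation, 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.344).

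**Figure D3:**
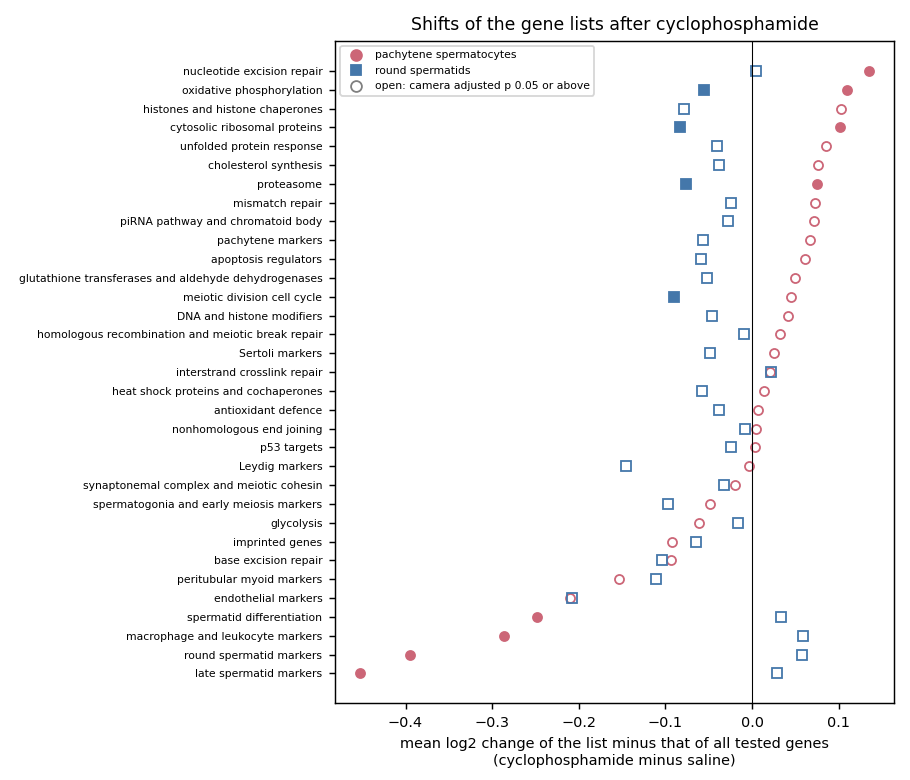
Shift of each gene list after cyclophosphamide, as the mean log2 change of the list minus that of all tested genes, in pachytene spermatocytes (circles, n = 5 and 5) and round spermatids (squares, n = 6 and 6); filled symbols passed camera at the preset correlation. Late spermatid markers lay at -0.45 in pachytene spermatocytes and 0.03 in round spermatids.

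The third comparison asked the same of round spermatids. Again no gene passed with limma among 18843 (smallest adjusted p = 1), and the values below are of genes that did not pass. The smallest unadjusted p on the higher side belonged to the orphan receptor Gpr26, Gal3st3 (0.66 ± 0.15), the defensin Defb39 (1.45 ± 0.33), the vomeronasal receptor Vom2r37 (1.99 ± 0.47) and Pdpr (0.47 ± 0.12), with n = 6 each. Gpr26 was not well above background on any saline array, so cyclophosphamide was at least 1.28-fold higher. Saline arrays with a signal well above background numbered 5 of 6 for Gal3st3, 1 for Defb39, 4 for Vom2r37, 1 for Pdpr and 5 for Pds5a, and treated arrays 5 for Gpr26, 5 for Pdpr and 2 for Pds5a. On the lower side they belonged to the slow muscle troponin Tnnt1 (-1.23 ± 0.28), Mettl25 (-0.53 ± 0.13), Drg1 (-0.48 ± 0.12), Tti1 (-0.37 ± 0.10) and the cohesin regulator Pds5a (-0.55 ± 0.15). At an unadjusted p under 0.05 there were 614 genes, 358 higher and 256 lower, and 65 and 40 of them differed by at least 1.5-fold. Independent genes would give 942 by chance, and 57 of 100 splits of the arrays, the real one included, gave at least 614. With slide as a block 0 genes passed (747 at the unadjusted level), and 0 passed within slide 1 or slide 2 (1012 and 618). For 95.7% of genes the 95% interval lay within 2-fold.

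In round spermatids 4 lists were slightly lower after cyclophosphamide, with 0 members passing over all genes or adjusted over the list alone. Ribosomal proteins were shifted by -0.08 (camera adjusted p = 5.08e-05), with 69 of 74 genes below 0, such as Rpsa (-0.40 ± 0.14) and Rpl13a (-0.25 ± 0.10). Meiotic division genes were shifted by -0.09 (adjusted p = 0.0119), with 36 of 43 below 0, such as Pkmyt1 (-0.28 ± 0.10) and Bub3 (-0.30 ± 0.15), the proteasome by -0.08 (adjusted p = 0.0141), with 34 of 43 below 0, such as Psma7 (-0.33 ± 0.17), and oxidative phosphorylation by -0.06 (adjusted p = 0.0211), with 57 of 71 below 0, such as Sdhc (-0.25 ± 0.13). Each had adjusted p = 0.9 with an estimated correlation, and fry called 0 of 33 lists (smallest adjusted p = 0.873). The treated arrays below the saline mean numbered 3, 4, 5 and 4 of 6. With slide as a block the shifts were -0.08, -0.09, -0.08 and -0.06. Within slide 1 they were 0.06, -0.21, -0.12 and -0.02, and within slide 2 -0.23, 0.03, -0.03 and -0.09, so the ribosomal and meiotic division lists changed sign between slides. No list passed without cyclophosphamide rat 27 or without saline rat 25, and 1 list passed without cyclophosphamide rat 25 or saline rat 15. Quantile normalization ended the oxidative phosphorylation call (adjusted p = 0.0721). In these fractions genes with a symbol outside the lists that were at least 4-fold higher in pachytene spermatocytes had a median change of -0.13. Per array the difference was -0.123, or -0.032 without saline rat 17.

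The remaining lists did not pass in round spermatids, and 0 of their members passed over all genes or adjusted over the list alone. Round spermatid markers were shifted by 0.06, pachytene markers by -0.06 and macrophage markers by 0.06 (camera adjusted p = 0.352, 0.355 and 0.609). Base excision repair was shifted by -0.10 (0.24), including Parp1 at -0.33 ± 0.14, and nucleotide excision repair by 0.01 (0.895). Homologous recombination was shifted by -0.009 (0.899), including Rpa2 at -0.33 ± 0.15, and crosslink repair by 0.02 (0.53), including Mus81 at 0.26 ± 0.12. The p53 targets were shifted by -0.02 (0.895), antioxidant genes by -0.04 (0.355), including Sod2 at -0.35 ± 0.14 and Srxn1 at 0.46 ± 0.19, and apoptosis genes by -0.06 (0.24), including Casp1 at 0.53 ± 0.20.

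The last comparison asked whether cyclophosphamide acted differently on the 2 cell types. The change of spermatid transcripts was lower in pachytene than in round spermatid fractions, the effect in pachytene minus that in round spermatids being -0.44 for round spermatid markers, -0.47 for late spermatid markers and -0.27 for spermatid differentiation (camera adjusted p = 6.49e-07, 0.000647 and 1.1e-06). Ribosomal proteins (0.19; adjusted p = 2.51e-07), oxidative phosphorylation (0.18; 9.22e-07), the proteasome (0.16; 0.000698), histones (0.19; 0.0331) and meiotic division (0.14; 0.0402) differed the other way. With an estimated correlation these 8 lists had adjusted p of 0.586 or more, and fry called 0 lists (smallest adjusted p = 0.297). Of their members 0 passed over all genes or adjusted over the list alone. With slide as a block the shifts were -0.45, -0.48 and -0.26 for the 3 spermatid lists and 0.21, 0.20, 0.19, 0.21 and 0.17 for the others, in the order named. Within slide 1 they were -0.51, -0.68, -0.46, -0.10, 0.03, 0.20, 0.26 and 0.05, and within slide 2 -0.11, -0.10, 0.04, 0.42, 0.30, 0.16, 0.30 and 0.11, so the spermatid differentiation and ribosomal lists changed sign on 1 slide. Leaving out an array ended the histone call for 9 of 22 arrays and the meiotic division call for 12.

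Single genes did not pass for that difference (0 of 19643 with limma, smallest adjusted p = 0.0585). At an unadjusted p under 0.05 there were 1502, where independent genes would give 982 by chance. Of 100 relabellings of the arrays 22, the real one included, gave at least 1502 (highest other 5551), so no excess over chance was shown. The smallest p among named genes belonged to Ptpro (-0.69 ± 0.14), Or1j16b, Pik3ap1 (-0.74 ± 0.16), the glutamine transporter Slc38a3 (-1.0 ± 0.25), Tex29 (-0.89 ± 0.23) and Slc45a1 (-0.84 ± 0.22), each with adjusted p = 0.634. Or1j16b was not well above background on any pachytene array, so its value rests on signal at background and is not given. With slide as a block 0 genes passed (1952 at the unadjusted level), within slide 1 there were 5 and within slide 2 there was 1. Across 17650 genes the effects in the 2 cell types correlated at r = -0.095 (rho = -0.257, genes are not independent replicates), and 37.7% had the same sign. Of 100 relabellings of the arrays 55 gave an r as far from 0, while rho and the share of the same sign were not set against relabellings. The r was -0.101 with slide as a block, -0.085 with quantile normalization and -0.178 with the stricter filter. Within a cell type, the round spermatid effects on slide 1 and slide 2 correlated at -0.049 and the pachytene effects on scan day 1 and scan day 2 at 0.205.

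**Figure D4:**
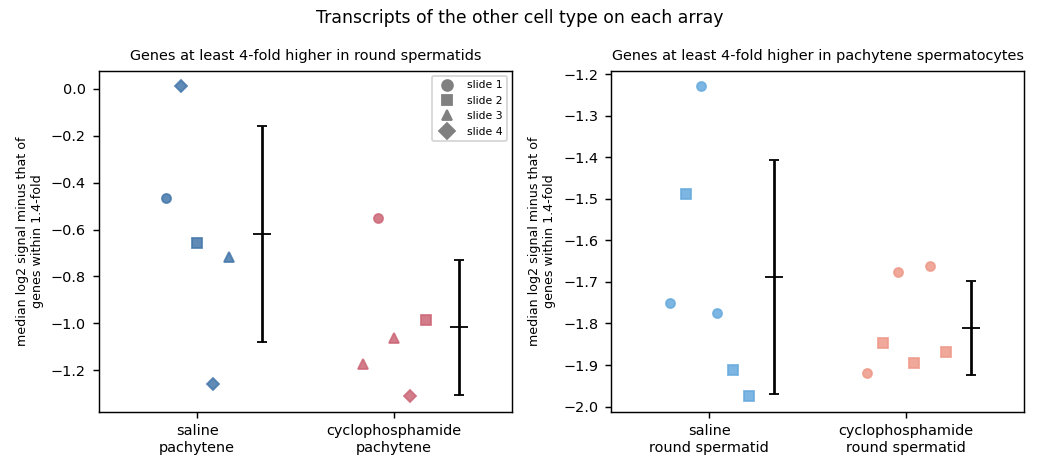
Median log2 signal, per array, of genes outside the lists that were at least 4-fold higher in the other cell type. That of genes within 1.4-fold between cell types is subtracted, both over genes with a symbol. Bars are the mean and SD. In pachytene fractions the measure was -1.02 after cyclophosphamide and -0.62 after saline (n = 5 each), and in round spermatid fractions -1.81 and -1.69 (n = 6 each). The differences of -0.398 and -0.123 became -0.241 without saline pachytene rat 16 and -0.032 without saline round spermatid rat 17.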

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

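The tests of carried-over round spermatids, of slide and scan day on spermatid transcripts, of slide 2 alone, of relabellings within slides, of the carry-over measure without each array and by slide, of somatic markers moving together and of other splits were chosen after the results were seen, as were the spreads set against the shifts, while those of saline rat 16, of carried-over pachytene spermatocytes and of scan day on macrophage markers were written beforehand.

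The first pattern is the lower level of spermatid transcripts in cyclophosphamide pachytene fractions, which no table excluded as an effect of the drug on these cells. A smaller carry-over of round spermatids is a candidate explanation. Outside the lists, 1173 genes with a symbol that were at least 4-fold higher in round spermatids had a median change of -0.399 relative to genes within 1.4-fold. Of these genes 98% were below 0, and the median went from -0.078 to -0.174, -0.388 and -0.514 as spermatid enrichment rose to at least 8-fold. Genes without a symbol were left out of this measure. Per array this measure was -1.016 ± 0.288 after cyclophosphamide and -0.618 ± 0.459 after saline (exact permutation p = 0.151 over 252 splits that ignore slide), and with slide as a block the difference of -0.398 was the lowest of 36 relabellings within slides (two-sided p = 0.167, since relabellings reached 0.539 the other way), while without saline rat 16 the difference over all slides was -0.241. With slide as a block the round spermatid list was shifted by -0.4 and still called (adjusted p = 0.545 with an estimated correlation in the fit without a block), and without saline rat 16 by -0.258, also still called. The shift was below 0 within each of 4 slides (mean -0.382, standard error 0.091 over slides) and within slides 1 to 3, which do not hold that rat (mean -0.294, standard error 0.037), which goes against slide and scan day and against that rat as the whole cause, but the standard errors over rats, 0.25 and 0.245, keep both open. Lower transcription of spermatid genes during pachytene would give the same values as less carry-over here, so the drug's effect on these cells stays open and untested.

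The second pattern is the lower level of ribosomal protein transcripts in cyclophosphamide round spermatid fractions. Whether a smaller carry-over of pachytene spermatocytes contributed stays open. Outside the lists, 755 genes with a symbol that were at least 4-fold higher in pachytene spermatocytes had a median change of -0.129. The steps were -0.045, -0.086, -0.128 and -0.132. Per array the measure was -1.812 ± 0.113 after cyclophosphamide and -1.689 ± 0.281 after saline (exact permutation p = 0.366 over 924 splits), but the difference of -0.123 fell to -0.032 without saline rat 17, where the ribosomal shift was -0.072 and still called (adjusted p = 0.9 with an estimated correlation over all arrays), and it was -0.168 on slide 1 and -0.079 on slide 2, the opposite order to that of the ribosomal shift. The ribosomal shift was 0.064 within slide 1, -0.229 within slide 2 and -0.08 with slide as a block, and whether it belonged to slide 2 alone stays open: the slides' effects on the mean of this list, picked for its opposite signs, differed by 0.337 (exact permutation p = 0.03 over 400 relabellings within slides), but p was 0.53 against the largest difference among all 33 lists. A drug effect on ribosomal genes stays open and was not tested apart from these.

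The third pattern is the higher level of macrophage and peritubular myoid markers in round spermatid fractions of saline rats. Scan day is argued against for the macrophage list, since its shift was 2.151 on the slides of scan day 1 alone. Somatic cells carried through the sedimentation, which parts cells by size, may contribute: macrophage markers moved together from array to array within groups (mean pairwise r 0.454, against a median of 0.007 and a 95th percentile of 0.104 for 1000 random sets), as did myoid (0.476), Sertoli (0.344) and Leydig markers (0.513). Lists that are not somatic did so too, such as late spermatid markers (0.855), round spermatid markers (0.656) and ribosomal proteins (0.525). Moving together therefore cannot tell carried cells from expression by the germ cells. The marker with the highest signal there, Lyz2, averaged 1.26 ± 0.65 in saline round spermatid and -1.77 ± 0.62 in saline pachytene fractions, and none of the 11 macrophage markers is on another list. Expression of these genes by the germ cells themselves stays open and was not tested.

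The cyclophosphamide effect differed between cell types for 8 lists by the camera test of the difference, as pachytene minus round spermatid. The values were -0.444 for round spermatid markers, -0.472 for late spermatid markers, -0.273 for spermatid differentiation, 0.193 for ribosomal proteins, 0.179 for oxidative phosphorylation, 0.16 for the proteasome, 0.19 for histones and 0.144 for meiotic division. With an estimated correlation 0 of these lists passed.

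Other splits of the same arrays, 100 per result, showed where chance can be excluded. For the 14598 genes that differed between cell types only 1 split, the real one, gave as many (highest other 10532), so chance can be excluded. For the 16 lists 4 splits gave as many (highest other 18), a share of 0.04, so other splits reached that count but seldom. Chance cannot be excluded for the 8 lists in pachytene spermatocytes (14 splits as large, highest other 14), the 4 lists in round spermatids (78 splits, highest other 11) or the 8 lists of the difference between effects (27 splits, highest other 14). The median over the other splits was 5, 6 and 5 lists in that order, so the 4 lists in round spermatids lay below it. For the counts of 0 genes every split, 100 of 100, gives at least as many by construction, so the splits say nothing about chance there. Among those splits the highest counts were 1426 in pachytene spermatocytes, 469 in round spermatids and 2463 for the difference, against a median of 0 each, and 14, 10 and 6 of 99 other splits gave any gene. A split with so many genes would point to a structure of the samples other than treatment, but what those splits share was not tested.

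Single arrays stood far from the others of their group, with the gap to the nearest array given as a share of the group's range. Chance alone gives about 1 in 20, and 5 of 160 tests of lists and array measures (8 by chance) and 20 of 294 tests of named genes (14.7 by chance) did so. The lists were Leydig markers (0.667) and glutathione transferases and aldehyde dehydrogenases (0.814) in cyclophosphamide round spermatids of rat 25, myoid markers in saline pachytene rat 26 (0.719) and nucleotide excision repair in cyclophosphamide pachytene rat 15 (0.77). The spot-to-spot variation of cyclophosphamide round spermatid rat 16 was 6.4% against 11.2% to 12.6% for the others (0.774). Cyclophosphamide pachytene rat 15 stood apart for Spata3 (0.778), Spem1 (0.733), Spaca4 (0.737), Polk (0.821) and Or52s1b (0.735). Saline pachytene rat 16 did so for Polk (0.716), Or10al4c (0.713) and H2bc1 (0.726), rat 26 for Gfpt2 (0.794) and Parp2 (0.789), and rat 13 for Tbce (0.71). In cyclophosphamide round spermatids it was rat 15 for Vom2r37 (0.665) and Rpa2 (0.751) and rat 14 for Or1j16b (0.732). In saline round spermatids it was rat 16 for Atosb (0.646) and Bub3 (0.67), rat 29 for Gmcl1 (0.636) and Parp2 (0.66), and rat 17 for Acsl3 (0.67) and Pms1 (0.645).

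The brightest spike-in control, which the comparisons do not use, differed between scan days on pachytene arrays by 3.02 on the log2 scale, at 3.96 ± 0.47 on day 1 (4 arrays) and 0.94 ± 0.08 on day 2 (6 arrays; exact permutation p = 0.00476 over 210 splits).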

How the results depend on the processing

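Added after the data were seen were each slide alone for lists, for the difference between effects and for cell types, slides 1 and 2 alone, the marker index as a covariate, and the settings for lists of the difference. Counts of genes that passed stayed at 0 for pachytene spermatocytes under each planned setting except within slides 1 to 4, which gave 5, 1, 1 and 4 genes, and the threshold of an unadjusted p under 0.05 with at least 1.5-fold, which gave 209. Among the genes within slides, named here after their values were seen, were Kcnh6 (4.91 within slide 2), Sema6c (-1.53 within slide 3), Cpne5 and Adtrp (2.65 and -3.70 within slide 4), and the rest had no symbol. In round spermatids the count stayed at 0 except for 105 at that looser threshold. Separate fits to the 6 round spermatid arrays of slide 1 and of slide 2 gave 1 and 4 genes. These were Nr5a2 (-2.487) on slide 1 and RT1-CE4 (2.347), Atp6v1g2 (2.086), RT1-CE11 (2.528) and a transcript without a symbol (5.067) on slide 2. Separate fits to the pachytene arrays of scan days 1 and 2 gave 0 and 2, both without a symbol. Of those 2, 1 was the same probe as the transcript on slide 2, also higher after cyclophosphamide (3.353). For the difference between effects the count was 5 within slide 1 and 1 within slide 2, Trim16 (3.79) being the 1 with a symbol. It was 0 to 1 when leaving out an array, the 1 being a transcript without a symbol (limma adjusted p = 0.00762 to 0.0471 without cyclophosphamide pachytene rat 16-2011, saline pachytene rat 25, cyclophosphamide round spermatid rat 26 or saline round spermatid rats 15 or 29). With the marker index as a covariate 0 genes passed in either cell type. Between cell types 12574 to 15664 genes passed over the planned settings with all slides, and 10433 within slide 1.

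List counts depended on the test. With an estimated correlation 0 lists passed in any comparison, and fry called 0, 0, 0 and 29 for pachytene spermatocytes, round spermatids, the difference and cell types. In pachytene spermatocytes quantile normalization gave 5 lists, slide 1 alone 1, and leaving out an array 5 (saline rat 25) to 10 (cyclophosphamide rat 16-2011). In round spermatids slide 1 alone gave 7, the replicate block 1, and leaving out an array 0 (cyclophosphamide rat 27 or saline rat 25) to 6 (saline rat 16), with 1 without cyclophosphamide rat 25 or saline rat 15 and 2 without saline rat 17. For the difference slide 2 alone gave 4 and the replicate block 5, and for cell types leaving out an array gave 14 to 17. Fewer arrays were behind each slide; for the other settings the cause was not tested.

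Directions reversed in 8 cases, and the cause was not tested. Within slide 1 these were macrophage markers (0.148) and ribosomal proteins (-0.044) in pachytene spermatocytes, ribosomal proteins in round spermatids (0.064) and for the difference (-0.105), and Pecam1 between cell types (0.021 against -0.71). Within slide 2 they were meiotic division in round spermatids (0.031) and spermatid differentiation for the difference (0.035). With the replicate block it was histones for the difference (-0.006). Otherwise named genes and list shifts kept their sign wherever the main value had passed.

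Equal rat numbers in the 2 treatments name different animals, since a rat received cyclophosphamide or saline. After removing group means, arrays of the same number correlated at -0.136 to 0.06 between treatments in round spermatids. Between cell types they did so at -0.088 to 0.381 in saline rats (other pairs -0.338 to 0.365) and at 0.002 to 0.162 in treated rats (other pairs -0.339 to 0.213). In treated rats pachytene arrays 16-2011 and 16-2012 were each paired with round spermatid array 16. With 3 such pairs per treatment these correlations do not settle whether equal numbers within a treatment name the same animal. The replicate block gave 0 genes in round spermatids (433 at an unadjusted p under 0.05), 0 for the difference (473) and 12692 between cell types, 12363 of them shared with the 14598. The block in round spermatids joined different animals. The block for the difference and for cell types joined treated pachytene arrays 16-2011 and 16-2012 as the same rat. No such block was run between treatments in pachytene spermatocytes, whose groups share only number 16. The value table was not run for the difference or for cell types, since it was centred within each cell type. Signal over background limits dim genes, 65.3% to 76.4% of probes being well above it.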

Other observations

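The spermatogonial list held genes that were higher in round spermatids than in pachytene spermatocytes of saline rats. Of 12 members 6 were higher and 3 lower, over all genes and adjusted over the list alone, and the list did not pass (shift 0.40; camera adjusted p = 0.342). Gfra1 and Ret, which form the receptor for the growth factor GDNF, were 7.12-fold and 4.83-fold higher in round spermatids, and the transcription factor Zbtb16 was at least 2.66-fold higher, since it was not well above background on any saline pachytene array. Id4 was 5.61-fold higher in pachytene spermatocytes. After cyclophosphamide this list was shifted by -0.05 in pachytene spermatocytes and -0.10 in round spermatids (adjusted p = 0.371 and 0.389).

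Single imprinted and cholesterol synthesis genes differed between the cell types, as did 75.2% of all tested genes, but neither list passed. Of 18 imprinted genes 10 were higher in round spermatids and 4 lower (shift 0.60; camera adjusted p = 0.132), with Peg12 7.10-fold, the growth inhibitor Cdkn1c 5.34-fold and the noncoding RNA H19 6.40-fold higher. In cholesterol synthesis 4 of 23 genes were higher and 12 lower (shift -0.56; adjusted p = 0.113), and the higher ones included Fdps (2.63-fold) and Sqle (2.35-fold). Counts adjusted over the list alone were the same. After cyclophosphamide imprinted genes were shifted by -0.09 and -0.07 in pachytene spermatocytes and round spermatids (adjusted p = 0.289 and 0.352), and cholesterol genes by 0.08 and -0.04 (adjusted p = 0.238 and 0.537).

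Per array, 36 measures were compared between treatments in each cell type by exact permutation tests. In pachytene spermatocytes the smallest p was 0.0159, for base excision repair (-0.013 ± 0.044 after cyclophosphamide and 0.081 ± 0.057 after saline), for the proteasome (1.964 ± 0.030 and 1.889 ± 0.032) and for the first principal component, and each had an adjusted p of 0.191. The lower mean of base excision repair was not shared by most members, since 9 of 17 were above 0 with a median change of 0.067. In round spermatids it was 0.0476, for heat shock genes (1.151 ± 0.034 and 1.208 ± 0.056; adjusted p = 0.791). The 4 red blood cell genes on the array averaged 0.29 ± 0.37 and 0.14 ± 0.12 in pachytene fractions after cyclophosphamide and saline, and -0.43 ± 0.50 and -0.66 ± 0.57 in round spermatid fractions.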
